A study of Oryza sativa with 8 samples.

How the data were processed

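Root RNA from 14-day-old rice seedlings was measured on Affymetrix rice arrays, with 1 sample per array. Wild-type plants of the variety Dongjin were set beside a line of that variety with a T-DNA insertion in Os02g31890, called the arid mutant here after the labels. Control roots stayed in hydroponic culture, and dehydrated roots lay on filter paper for 90 min. The titles place the 8 arrays in 4 groups of 2. Nothing in the labels says whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

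The deposited table holds log2 expression values that the authors computed, 1 column per array, for 57381 probe sets. GCRMA and RMA are named per the submitters' processing notes, without versions. Which of them made the values, and with which settings, is not given in the sources used here. GCRMA subtracts a background modelled from probe sequence, and both methods bring the arrays to a shared distribution before probes are summarised. The values bear the marks of such a background step. The lowest value was 2.19, 43.2% of all values were equal to it, and 19933 probe sets (34.8%) held it on all 8 arrays. Values within 0.1 of it are called the floor here. A further 4307 probe sets (7.52%) held 1 repeated value above the floor on at least 4 arrays. Where every array of a group lay at the floor, a log2 change is a lower bound and is written as "at least". Group means up to 1 above the lowest value are called near background, where the size of a change is poorly fixed. The shared distribution removes any change in total mRNA between groups.

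The 123 control probe sets were left out of the tests, which left 57258. A table of GEO's platform annotation pairs 22436 of these with 1 gene, 95 with several genes and 34727 with none. The genes number 17905, and 3444 of them have several probe sets, in which case the probe set with the highest mean over all arrays stands for the gene. Symbols come from a RefSeq gene table of the assembly ASM3414082v1, which holds all 17905 genes and gives a symbol or synonym other than a number for 2457. The table was used for names and for which genes are neighbours. It holds no product descriptions, so the gene lists, planned as searches of descriptions, were made from symbols and synonyms, and a gene counted as informatively named if it had one. The targeted gene was not analysed here, because nothing in the tables used here pairs a probe set with Os02g31890.

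A linear model with 1 mean per group was fitted to the deposited log2 values of all 8 arrays in limma 3.58.1 (R 4.3.3), with moderated variances that follow an intensity trend. Between them, the 4 groups leave 4 residual degrees of freedom, to which the moderation adds 0.61. The 5 contrasts were dehydration minus control in each genotype, arid minus wild type in each condition, and the difference between the dehydration responses of the genotypes (the interaction). Tests were two-sided, Benjamini-Hochberg adjustment was made within each contrast, and an adjusted p under 0.05 counted as a call. Errors of log2 changes are limma standard errors. With 2 arrays per group, the number of arrays limits the precision. No batch, date or scan label was given for any array.

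Of the 30 gene lists fixed beforehand, 26 had at least 5 measured genes and were tested with limma's camera, which asks whether a list's genes moved more than the other genes. It was run with a preset correlation between genes of 0.01, and again with an estimated correlation. The ABA and dehydration reference genes, 32 known responsive genes of which 22 were matched, share 5 genes with the list of LEA proteins and dehydrins, 4 with the PP2C protein phosphatases, 4 with the DREB and ERF transcription factors and 2 each with the lists of NAC transcription factors, ABA synthesis and breakdown, and osmoprotectant synthesis. The list of ARID domain genes had 0 matched genes and gave no result. The signs of a list's median, mean and test differed in 23 of the 130 list tests, 0 of which were calls. Of the 39 calls with the preset correlation, 2 held with an estimated correlation, both of the reference genes under dehydration. The sign of the list median was the same for every call with quantile normalization and with median centring of the arrays, while the size of some medians moved.

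Named genes were chosen by rule. They are the 10 largest increases and decreases per contrast among informatively named genes that were called and whose arrays did not overlap between the groups, up to 4 called members of each list with the largest changes, and all reference genes. The groups, contrasts, lists, naming rule and the alternatives listed next were fixed before the data were examined. Genes named outside the rule are said to be so. Alternatives tried were the replicate number as a block, a filter that keeps the probe sets with a mean above the median, quantile normalization, median centring, fits without the intensity trend, with robust variances, with array weights, on the compared groups alone, adjustment over all contrasts, a minimum log2 change of 1, genes in place of probe sets, and leaving out each array. Others were added after seeing the data: a filter on floor values, other pairings of the replicate numbers, and fits with the dehydrated arrays of 1 replicate number only.

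The fit was tested on data simulated for the comparison of dehydrated with control wild-type roots, with 200 of 57258 probe sets changed. It called 7 of 100 probe sets changed by a log2 of 1 and 24 of 100 changed by a log2 of 2, with 51 false calls, 45 of them among the dimmer probe sets. With the 28625 brighter probe sets alone it called 4 and 20 of 100, with 3 false calls. The total of calls in each comparison is therefore given with the total after the filter on dim probe sets, which also moved the counts within several lists. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for the tables and plots, and version 1.17.8 of data.table for reading in R.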

Results

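Transcripts were measured in roots of wild-type and arid mutant rice, each kept in hydroponic culture or dehydrated for 90 min, with 2 arrays per group. The array medians lay between 2.33 and 2.37 on the log2 scale, and 42.2% to 43.9% of the probe sets of an array lay at the lowest value. Over the brighter probe sets (mean above the median), which are not independent replicates, the replicates of a group correlated with r = 0.986 in wild-type control, 0.982 in arid control, 0.937 in dehydrated wild-type and 0.930 in dehydrated arid roots. The SD of the difference between replicates was 0.547 and 0.623 in the control groups of wild type and mutant, and 1.16 and 1.22 in their dehydrated groups. The dehydrated arrays numbered 1 stood apart from those numbered 2 in heat shock genes. The median difference over 43 heat shock proteins and factors was 2.72 in wild type and 1.97 in the mutant, against −0.31 and 0.20 between the control replicates.

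The level of the targeted gene was not analysed here, so the genotype labels were checked with the foreign reporter sequences that the array carries, a check chosen after the values were seen. Of the 64 reporter probe sets, 60 lay within 1 of the lowest value on all arrays. A single reporter probe set was over 1 higher on every arid array than on every wild-type array, at 14.44 to 14.88 against 2.32 to 2.52. In arid roots it was higher by 12.11 ± 0.098 under control conditions (limma, adjusted p = 1.3e-05) and by 12.31 ± 0.098 after dehydration (adjusted p = 1.61e-05). The probe set shows which arrays carry that foreign sequence and says nothing of the level of Os02g31890.

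Control probe sets showed how the samples differed outside the tested genes. The 3′ minus 5′ difference of the GAPDH probe sets, a sign of RNA integrity, ranged from 1.93 to 2.52 and that of actin from 2.18 to 2.90, with overlapping ranges of control and dehydrated arrays. The same difference for cyclophilin was 1.54 to 1.73 on control arrays and 0.70 to 1.28 on dehydrated arrays. Probe sets for ribosomal RNA were also brighter on the dehydrated arrays, with the 5.8S probe set at 5.86 to 6.47 on control and 8.39 to 9.62 on dehydrated arrays. The rise differed between the genotypes for 25S, at 2.06 in wild type and 0.50 in the mutant, and for 28S, at 2.06 and 0.72. The BioB spike had a mean of 7.78 ± 0.099 in dehydrated arid roots and of 6.92 to 7.04 in the other groups (SD, n = 2).

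The comparison of dehydrated with control wild-type roots asks which transcripts respond to 90 min of water loss. The largest fitted named increase was that of OsHox24 (LOC4330155), a homeodomain-leucine zipper transcription factor, which rose by 11.36 ± 0.851 (adjusted p = 0.0136), from 2.69 ± 0.007 to 14.05 ± 0.474 (mean ± SD, n = 2). The PP2C phosphatases OsPP2C59 and OsPP2C30, members of a family that holds negative regulators of abscisic acid (ABA) signalling, rose by 10.74 ± 1.18 (adjusted p = 0.0285) and 9.96 ± 0.932 (adjusted p = 0.0212). The dehydrin RAB16B rose by 8.49 ± 1.04 (adjusted p = 0.0344) and OsPSY3, a phytoene synthase of carotenoid synthesis, by 8.32 ± 0.474 (adjusted p = 0.00781). ACO1 (LOC4347225), an oxidase of the last step of ethylene synthesis, rose by 7.48 ± 0.200 (adjusted p = 0.000909). The other 5 of the largest named increases were OsELA3 (10.09), OsC3H10 (8.55), OsHox22 (8.31), OsPM19L1 (8.11) and the heat shock factor HSF07 (7.70). The largest named decreases were those of the MYB factor MYBAS1, which fell by 5.65 ± 0.697 (adjusted p = 0.0352), and of the sodium transporter OsHKT1;5, which fell by 5.19 ± 0.460 (adjusted p = 0.0195). Also among them were OsPP2C12 (−4.57), BZIP06 (−4.52), BHLH004 (−4.47), OsC3H9 (−4.37), G1L9 (−3.99), OsCASPL1B1 (−3.86), OsGT7 (−3.55) and the ethylene receptor gene OsETR2 (−3.28). OsHox24, OsPP2C59, OsELA3 and OsC3H10 lay near background in control roots, and BHLH004, OsC3H9 and OsCASPL1B1 in dehydrated roots, so the sizes of these changes and their order are poorly fixed.

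Of the 22 ABA and dehydration reference genes, 12 rose, 0 fell and 10 did not pass the test in wild type. Adjusted over the list alone, 18 rose. The list median was 3.62 with 21 genes higher (camera, adjusted p = 1.79e-15, and adjusted p = 0.0202 with an estimated correlation). The transcription factors BZIP23 and NAC048 rose by 3.20 ± 0.116 (adjusted p = 0.00241) and 3.82 ± 0.215 (adjusted p = 0.00751). RAB16D, at 6.68 ± 1.26, ABA8OX2, at 5.03 ± 0.797, and P5CS1, at −0.12 ± 0.208, were among those that did not pass. All 8 LEA proteins and dehydrins were higher, with 6 that rose over all probe sets and 8 adjusted over the list alone. Their median was 7.02 (camera, adjusted p = 5.58e-09, adjusted p = 0.21 with an estimated correlation), and RAB21 and EM rose by 7.51 and 7.43. Of 56 PP2C protein phosphatases, 12 rose, 2 fell and 42 did not pass (18 and 2 adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.0502 with an estimated correlation). All 3 genes of ABA synthesis and breakdown were higher with a median of 3.68, of which 0 passed over all probe sets and 3 adjusted over the list alone. Under the filter on dim probe sets 16 reference genes, 8 LEA proteins, 13 PP2C phosphatases and 2 genes of ABA synthesis and breakdown rose. The kinase gene OsSAPK10 rose by 2.07 ± 0.171 and was the only one of 11 ABA receptors and SnRK2 kinases to pass.

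**Figure D1:**
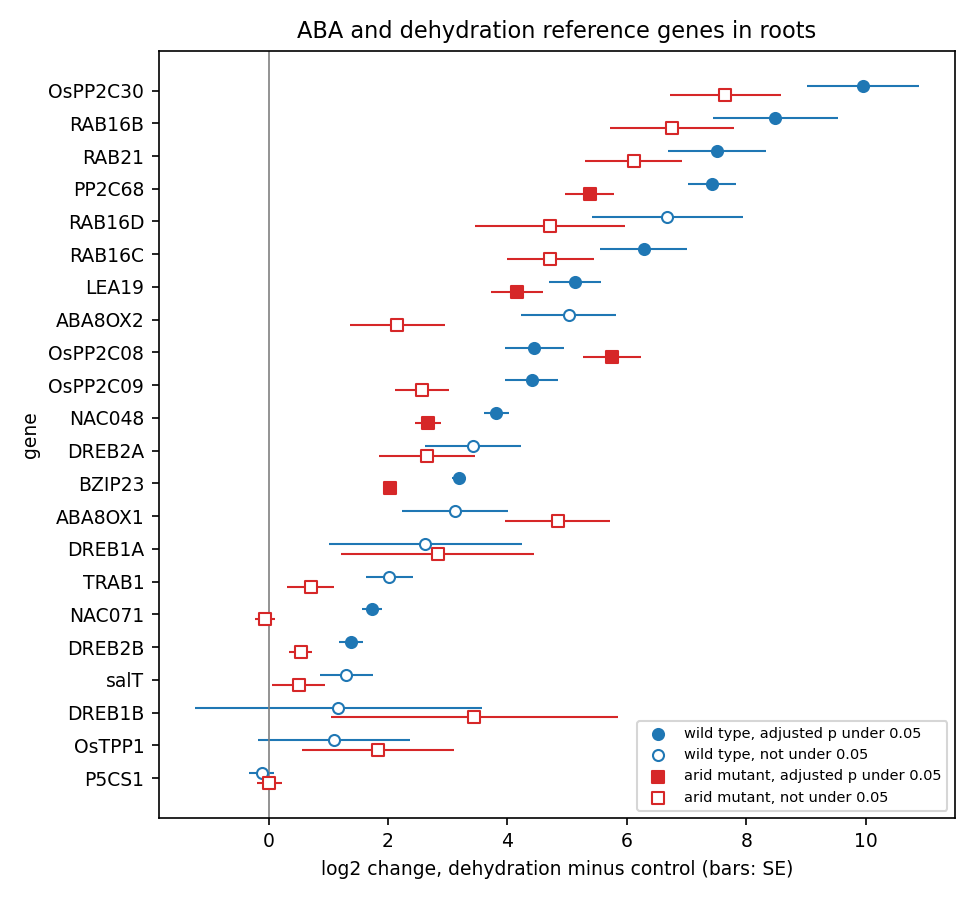
The log2 change from control to dehydration is plotted for each of the 22 ABA and dehydration reference genes, with circles for wild type and squares for the arid mutant, bars for the limma standard error, and filled symbols for an adjusted p under 0.05. Changes reach 9.96 in wild type and 7.65 in the mutant for OsPP2C30, with 12 filled symbols in wild type and 5 in the mutant.

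Further lists moved in wild-type roots, each without a call once the correlation was estimated. Of 43 heat shock proteins and factors, 4 rose and 39 did not pass, with a median of 1.27 (camera, adjusted p = 0.000254, adjusted p = 0.581 with an estimated correlation). The 4 were the factors HSF07, HSF03 at 4.53, HSF02 at 3.51 or more, being at the floor in control roots, and HSF09 at 2.94. The median of this list against the control mean was 3.06 with dehydrated replicate 1 and 0.03 with replicate 2. Of 8 NAC transcription factors 2 rose (camera, adjusted p = 0.00368, adjusted p = 0.21 with an estimated correlation), and of 10 DREB and ERF transcription factors DREB2B alone rose, by 1.39 (camera, adjusted p = 0.0249, adjusted p = 0.516 with an estimated correlation). Of 13 genes of osmoprotectant synthesis 3 rose, the raffinose synthase gene RFS by 3.77, OsTPP9 by 2.97 and OsTPP2 by 1.83 (camera, adjusted p = 0.0159, adjusted p = 0.21 with an estimated correlation). The 36 genes of jasmonate synthesis and JAZ repressors had a median of 0.59 (camera, adjusted p = 0.0051, adjusted p = 0.586 with an estimated correlation), and against the control mean it was −0.04 with dehydrated replicate 1 and 1.42 with replicate 2. The 1 member that passed was OsTIFY2b, a GATA-type factor with a TIFY motif and not a JAZ repressor, which fell by 0.97, and with the filter on dim probe sets 4 rose and 1 fell. The 15 pathogenesis-related proteins and chitinases had a median of 0.48 with 0 calls and 2 genes at an unadjusted p under 0.05 (camera, adjusted p = 0.0226, adjusted p = 0.454 with an estimated correlation). Of 9 shoot and photosynthesis genes, kept as markers of another tissue, OEE3 rose by 4.43 and LHCP by at least 1.26 from the floor (camera, adjusted p = 0.0186, adjusted p = 0.21 with an estimated correlation). Medians against the control mean were also larger with dehydrated replicate 2 than with replicate 1 for the osmoprotectant genes (1.29 and 0.10), the DREB and ERF factors (1.41 and 0.43), the NAC factors (1.83 and 1.07) and the pathogenesis-related proteins (0.70 and 0.15).

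Lower in dehydrated wild-type roots were 22 of 23 cytosolic ribosomal proteins, with a median of −0.69 and 1 call, RPS10-1 at −0.87 (camera, adjusted p = 0.00439, adjusted p = 0.603 with an estimated correlation). Of 12 histones and mitotic cyclins, 11 were lower and 3 passed, H2B.7 at −1.39, H2B.5 at −1.21 and H2B.6 at −1.02, and the list itself did not pass (camera, adjusted p = 0.0536). The remaining tested lists were not called, with adjusted p-values from 0.0536 to 0.979. Among them, 5 of 58 auxin response and transport genes rose and 2 fell, led by IAA9 at 5.86 and GH3-8 at 3.03, or 9 and 4 with the filter on dim probe sets. Of 26 cytokinin response genes LOG and ORR1 rose by 4.34 and 1.69, of 23 iron uptake genes IRO3 rose by 3.63, and of 30 expansins and xyloglucan endotransglucosylases EXLA2 rose by 6.86. Of 3 ethylene synthesis genes ACO1 rose, and of 17 nitrogen uptake genes AMT3-3 fell by 3.06 to near background. The single called member of the 11 seed storage genes, GLB1, fell by 0.96. It was placed in that list by its symbol, its product is not given in the tables used here, and it stood at 12.30 in control roots. By limma 0 genes were called among the 6 WRKY factors, 25 aquaporins, 3 class III peroxidases, 14 antioxidant enzymes, 6 glutathione S-transferases, 16 phosphate transport genes, 12 anaerobic response genes and 5 lipid transfer proteins. With the genes of ABA synthesis and the pathogenesis-related proteins, these lists hold 105 genes, of which 13 were higher and 11 lower at an unadjusted p under 0.05. Adjusted over the list alone, 2 WRKY factors rose, and 1 phosphate transport gene rose and 4 fell.

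Over all probe sets, 719 rose and 966 fell with dehydration in wild type, 1685 in all of 57258. An unadjusted p under 0.05 was found for 9260, against 2863 expected by chance over all 57258. That expectation is too high, since the 19933 probe sets at the lowest value on all arrays cannot reach such a p. With the filter on dim probe sets 1459 rose and 2250 fell, and counted as genes 440 rose and 574 fell. Fitted with the dehydrated arrays numbered 1 alone the count was 7110, and with those numbered 2 alone 5412, where the lone dehydrated array of each genotype was assumed to vary like the control arrays. With the arrays numbered 1 alone 3992 rose and 3118 fell, and with those numbered 2 alone 3233 and 2179. The count was 86 when only the 4 wild-type arrays were fitted (51 rose and 35 fell) and 315 without either arid control array (159 and 156, or 158 and 157). It was 3140 and 3033 without replicates 1 and 2 of dehydrated wild type, and there more rose than fell (2087 and 1053, 2034 and 999). More fell than rose without either replicate of wild-type control or of dehydrated arid roots. Both replicates of a group gave the same direction, so the turn followed the group left with 1 array and not a particular array. The split was 703 and 716 with quantile normalization, 272 and 235 with the replicate number as a block, and 366 and 331 with robust variances. Of the 56 named genes called here, 15 stayed called without either arid control array, 20 and 27 without wild-type control replicates 1 and 2, 36 and 37 without dehydrated wild-type replicates 1 and 2, and 47 and 46 without dehydrated arid replicates 1 and 2. When only the wild-type arrays were fitted, 1 of 56 stayed called.

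In the same comparison in the arid mutant, OsHox24 again had the largest fitted named increase. From near background it rose by 9.23 ± 0.851 (adjusted p = 0.0352), from 2.98 ± 0.071 to 12.21 ± 1.76 (mean ± SD, n = 2). OsITPK4, an inositol phosphate kinase, rose by 6.93 ± 0.700 (adjusted p = 0.0416), the expansin-like gene EXLA2 by 6.74 ± 0.769 (adjusted p = 0.0497) and the LEA gene EM by 6.21 ± 0.630 (adjusted p = 0.0421). OsPP2C08 rose by 5.75, HSF07 by 5.65, the calmodulin-like gene CML15 by 5.51, PP2C68 by 5.38, RFS by 5.09 ± 0.323 (adjusted p = 0.0191) and JAZ10 by 4.69. OsP5CS2, an enzyme of proline synthesis, rose by at least 2.91 ± 0.171 from the floor (adjusted p = 0.016). OsHKT1;5 fell by 4.35 ± 0.460 (adjusted p = 0.0435). Smaller decreases were those of CML29 (−2.56), OsHox8 (−2.39), IAA25 (−2.07), OsPP2C28 (−1.59), OsSTLP3 (−1.57), OsCOI1b (−1.01), GLB1 (−0.57) and OsQSOX1 (−0.55). OsBAK1-7 was called at −0.93, with 1 value of 7.28 repeated on every array outside the arid control group. With the filter on dim probe sets OsBAK1-7 and GLB1 were no longer called (adjusted p = 0.0622 and 0.057).

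Of the 22 reference genes, 5 rose in the mutant (BZIP23, NAC048, LEA19, OsPP2C08 and PP2C68), 0 fell and 17 did not pass, and 13 rose adjusted over the list alone. Their median was 2.75 with 21 genes higher (camera, adjusted p = 8.14e-12, and adjusted p = 0.0341 with an estimated correlation). All 8 LEA proteins and dehydrins were higher with a median of 5.42, of which LEA19 and EM passed, and 8 adjusted over the list alone (camera, adjusted p = 4.5e-08, adjusted p = 0.256 with an estimated correlation). Of 56 PP2C phosphatases 6 rose and 1 fell, or 18 and 3 adjusted over the list alone (camera, adjusted p = 0.00026, adjusted p = 0.09 with an estimated correlation). Under the filter on dim probe sets 11 reference genes and 5 LEA proteins rose, and of the PP2C phosphatases 13 rose and 2 fell. The genes of jasmonate synthesis and JAZ repressors had a median of 1.32 with 30 of 36 higher, and 11 rose and 2 fell adjusted over the list alone against the 1 call of JAZ10 over all probe sets, or 4 with the filter (camera, adjusted p = 5.32e-06, adjusted p = 0.614 with an estimated correlation). NAC factors had a median of 2.03 (camera, adjusted p = 0.0128, adjusted p = 0.327 with an estimated correlation, 0.0966 with every probe set of each gene in place of 1). DREB and ERF factors had a median of 1.18 with 0 calls and 2 genes at an unadjusted p under 0.05 (adjusted p = 0.0225, adjusted p = 0.706 with an estimated correlation). Osmoprotectant genes, with 2 that rose of 13, and pathogenesis-related proteins were also called, at adjusted p = 0.03 and 0.00692 (adjusted p = 0.327 and 0.453 with an estimated correlation). Of 23 ribosomal proteins 21 were lower, with a median of −0.63, 0 calls and 4 genes at an unadjusted p under 0.05 (camera, adjusted p = 0.00119, adjusted p = 0.742 with an estimated correlation). The 43 heat shock genes were not called (adjusted p = 0.151), and their median against control was 1.71 with replicate 1 and −0.44 with replicate 2. With the same replicates the medians were 1.20 and 2.01 for the jasmonate genes, 0.33 and 1.40 for the DREB and ERF factors, 0.00 and 0.82 for the osmoprotectant genes, 1.79 and 1.09 for the NAC factors, and −0.99 and −0.25 for the ribosomal proteins.

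In the mutant 327 probe sets rose and 230 fell with dehydration, 557 in all, with 6879 at an unadjusted p under 0.05. Median centring of the arrays moved this split to 474 and 201. With the filter on dim probe sets 776 rose and 437 fell, and counted as genes 218 rose and 92 fell. The count was 5022 with only the dehydrated arrays numbered 1 (2880 rose and 2142 fell) and 2032 with only those numbered 2 (1432 and 600). It was 46 when only the 4 arid arrays were fitted (22 and 24), and 2462 and 1224 without arid control replicates 1 and 2, where far more fell than rose (381 and 2081, 211 and 1013). It was 1067 and 2550 without dehydrated arid replicates 1 and 2 (806 and 261, 1501 and 1049), 75 and 74 without the wild-type control replicates (35 and 40, 35 and 39), and 172 and 173 without the dehydrated wild-type replicates (103 and 69, 104 and 69). Here too both replicates of a group gave the same direction, so the turn followed the group left with 1 array and not a particular array. Of the 30 named genes called here, 0 stayed called without either wild-type control array, 6 without either dehydrated wild-type array, 22 and 12 without arid control replicates 1 and 2, and 15 and 27 without dehydrated arid replicates 1 and 2. Fitted with only the arid arrays, 1 of 30 stayed called.

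The dehydration responses of the genotypes, which share no arrays, correlated across probe sets with Pearson r = 0.711 and Spearman rho = 0.548, where probe sets are not independent replicates. The responses are not free of common deviations. Differences between replicates 1 and 2 correlated at 0.606 between the dehydrated groups over the brighter probe sets. Such deviations may raise the correlation and the number of shared calls. Calls shared by both genotypes were 235 increases, against 4.11 in independent lists of these sizes, and 96 decreases, against 3.88, an expectation that leaves out the variances shared by both tests, while 2 probe sets were called in opposite directions. Shared calls numbered 567 and 233 with the filter on dim probe sets, and with fits on the compared groups alone 3 and 0. Leaving out 1 array moved the number of shared calls widely. Both arrays of a group gave similar numbers, except in the dehydrated arid group, so the number depended mostly on which group was left with 1 array. The correlation was 0.485 without dehydrated arid replicate 1 and 0.613 without dehydrated wild-type replicate 2.

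The comparison of arid with wild-type roots under control conditions asks what the mutant changes in unstressed roots. Higher in the mutant were JAZ2 (LOC4342421), a repressor of jasmonate signalling, by 8.29 ± 0.657 (adjusted p = 0.0198), from 2.38 ± 0.269 to 10.67 ± 0.184 (mean ± SD, n = 2), and OsCPS2, a diterpene synthase, by 3.96 ± 0.304 (adjusted p = 0.0184). OsPSY3 was higher by 4.12 ± 0.474 (adjusted p = 0.0454), ACO1 by 3.49 ± 0.200 (adjusted p = 0.00967), the laccases LAC19 and LAC15 by 3.47 and 2.56, and HSF03 by 2.78. OsbZIP49, NAC071 and IAA20 (LOC4340245) completed the largest named increases, at 1.77, 1.69 and 1.25. Lower in the mutant were the sugar transporter gene OsSWEET1a, at −6.82 ± 0.610 (adjusted p = 0.0279), the kinase gene OsCIPK18, at −6.77 ± 0.487 (adjusted p = 0.0165), and the β-tubulin genes OsTUB8, at −6.13 ± 0.562 (adjusted p = 0.0291), and OSTB-16, at −4.63 ± 0.398 (adjusted p = 0.0254). Also lower were the cellulase-family gene OsCel9A at −6.04, BHLH003 at −5.84, HOS66 at −5.19, OsGT43A at −4.94, the kinesin gene KIN8B at −4.61 and the β-glucosidase gene BGLU6 at −4.59. JAZ2 and OsCPS2 lay near background in wild-type control roots, and OsSWEET1a, OsCIPK18, OsCel9A and KIN8B in arid control roots, so the sizes of these differences are poorly fixed. The actin 3′ control probe set moved with these genes, at 13.25 ± 0.057 in wild-type and 11.73 ± 0.057 in arid control roots (mean ± SD, n = 2).

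Genes of cell wall extension were lower in the mutant as a group. Of 30 expansins and xyloglucan endotransglucosylases 28 were lower, with a median of −1.89, of which EXPA5 at −4.15 and OsXTH8 at −3.17 passed, with 5 under the filter on dim probe sets and 9 adjusted over the list alone (camera, adjusted p = 2.16e-06, adjusted p = 0.814 with an estimated correlation). Of 12 histones and mitotic cyclins 11 were lower with a median of −0.91, 0 calls and 6 genes at an unadjusted p under 0.05 (camera, adjusted p = 0.00414, adjusted p = 0.814 with an estimated correlation). Of 23 ribosomal proteins 21 were lower, with a median of −0.44, 0 calls and 2 at an unadjusted p under 0.05 (camera, adjusted p = 0.0276, adjusted p = 0.864 with an estimated correlation). Higher in the mutant were 37 of 43 heat shock genes, with a median of 0.86 and HSF03 as the call (camera, adjusted p = 0.0227, adjusted p = 0.864 with an estimated correlation). Of the 22 reference genes 19 were higher, with a median of 0.97, and NAC071 and BZIP23 passed, the latter at 1.00 ± 0.116, while 4 were higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.00414, adjusted p = 0.441 with an estimated correlation). Single calls elsewhere were WRKY51 at 1.10, the aquaporin OsPIP2;6 at −3.33, AMT3-3 at −2.62, IAA8 with both groups near background and GLB1 at −0.47, the last not called with the filter on dim probe sets (adjusted p = 0.0767). The other tested lists were not called, with adjusted p-values from 0.0769 to 0.974.

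Between the control groups 265 probe sets were higher and 455 lower in the mutant, 720 in all, with 6481 at an unadjusted p under 0.05. Median centring moved the split to 256 and 737. With the filter on dim probe sets 458 were higher and 1128 lower, and counted as genes 114 and 277. The count was 112 when only the 4 control arrays were fitted (49 higher and 63 lower). It was 2602 and 1282 without arid control replicates 1 and 2, and there far more were higher (2085 and 517, 1015 and 267). It was 1342 and 1666 without wild-type control replicates 1 and 2 (190 and 1152, 316 and 1350), 339 and 326 without the dehydrated arid replicates (147 and 192, 144 and 182), and 345 and 338 without the dehydrated wild-type replicates (222 and 219 of them lower). The excess of lower probe sets thus turned around without either arid control array. Of the 28 named genes called here, 19 and 11 stayed called without arid control replicates 1 and 2, 10 and 16 without wild-type control replicates 1 and 2, 7 without either dehydrated arid array, 6 without either dehydrated wild-type array, and 0 when only the control arrays were fitted.

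After dehydration fewer named genes separated the genotypes. JAZ2 was higher in the mutant by 8.54 ± 0.657 (adjusted p = 0.0439), OsCPS2 by at least 5.56 ± 0.304 over the floor (adjusted p = 0.0165), LAC15 by 4.11 ± 0.262 (adjusted p = 0.0261) and OsP5CS2 by 2.47 ± 0.171 over wild-type roots near background (adjusted p = 0.0337). The homeodomain-leucine zipper gene OsHox14 was lower at −5.23 ± 0.196 (adjusted p = 0.00627), BGLU6 at −3.28 ± 0.206 (adjusted p = 0.0252), the calmodulin-like gene CML11 at −1.87 and PIP5K at −0.78, which was not called with the filter on dim probe sets (adjusted p = 0.115). JAZ2, OsCPS2, LAC15, OsHox14, BGLU6 and CML11 were also called between the control groups, with the same direction, OsHox14 there at −3.30 and CML11 at −2.45. So were 2 probe sets of LOC4331398, named after its values were seen, which were higher in the mutant by 11.83 and 11.21 in control and by 11.37 and 10.72 in dehydrated roots, over wild-type values near background.

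**Figure D2:**
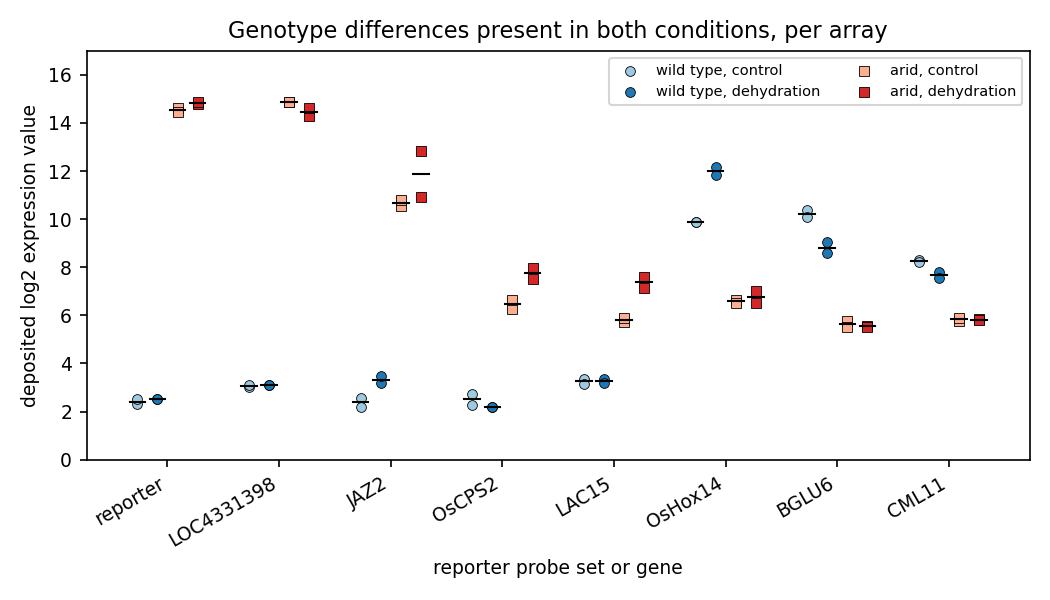
Deposited log2 values are plotted per array for the reporter probe set and 7 genes that differ between the genotypes in both conditions, with circles for wild-type and squares for arid arrays, lighter for control and darker for dehydration, and a bar at each group mean. The reporter stands at 14.44 to 14.88 on arid arrays and 2.32 to 2.52 on wild-type arrays, and OsHox14 is lower on all 4 arid arrays.

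Of 30 expansins and xyloglucan endotransglucosylases 27 were lower in dehydrated arid roots, with a median of −0.72, 4 genes at an unadjusted p under 0.05 and 0 calls over all probe sets, or 3 adjusted over the list alone (camera, adjusted p = 1.14e-06, adjusted p = 0.569 with an estimated correlation). Of 25 aquaporins 20 were lower with a median of −0.54 (camera, adjusted p = 0.00114, adjusted p = 0.569 with an estimated correlation). Of 58 auxin genes 37 were lower, with a median of −0.06, or −0.20 after quantile normalization (camera, adjusted p = 0.00267, adjusted p = 0.569 with an estimated correlation). Ribosomal proteins, 20 of 23 lower, and shoot genes, 7 of 9 lower, had medians of −0.21 and −0.18 (camera, adjusted p = 0.0181 and 0.0444, adjusted p = 0.816 and 0.569 with an estimated correlation), the latter −0.42 after quantile normalization. In these lists 0 genes were called over all probe sets. The 22 reference genes had a median of −0.09, and the list was not called (adjusted p = 0.256).

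Between the dehydrated groups 68 probe sets were higher and 47 lower in the mutant, 115 in all, with 4103 at an unadjusted p under 0.05. With the filter on dim probe sets 83 were higher and 58 lower, and counted as genes 25 and 17. The count was 3494 with only the dehydrated arrays numbered 1 (1539 higher and 1955 lower), 3493 with only those numbered 2 (1388 and 2105), and 51 when only the 4 dehydrated arrays were fitted (27 and 24). It was 43 and 46 without arid control replicates 1 and 2 (21 and 22, 21 and 25), 48 and 46 without wild-type control replicates 1 and 2 (24 and 24, 23 and 23), and 980 and 1148 without the dehydrated arid replicates (782 and 198, 968 and 180). Without either dehydrated wild-type replicate far more were lower, and without either dehydrated arid replicate far more were higher. The direction of the split thus followed the group left with 1 array and not a particular array. Of the 8 named genes called here, 1 stayed called with array weights and 0 when only the dehydrated arrays were fitted. The calls were also lost without any 1 of the control arrays, so they rest on the smaller spread of the control replicates.

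The interaction asks whether the dehydration response differs between the genotypes. ACO1 responded less in the mutant, by −3.75 ± 0.283 (adjusted p = 0.0348), having risen by 7.48 in wild type and by 3.73 in the mutant, to 12.04 ± 0.396 and 11.78 ± 0.049 (mean ± SD, n = 2). BHLH004 and OsC3H9 fell in wild type and were called (adjusted p = 0.0348 and 0.0411), with group means of 7.24 and 7.14 in wild-type control roots and of 2.43 to 2.98, near background, in the other groups, so their response in the mutant was not measurable. OsCslF8 and CHLP were above the floor only in wild-type control roots, at 4.99 ± 0.064 and 4.13 ± 0.092 (interaction, adjusted p = 0.00014 and 0.00167), and their response in the mutant, at the floor in both conditions, was likewise not measurable. OsP5CS2 rose from the floor in the mutant and held 1 repeated value of 2.67, near background, in wild type, with a fitted difference of 2.91 ± 0.241 (adjusted p = 0.0462). CML27 gave a difference of 1.71 ± 0.124 (adjusted p = 0.0321), with 10.41 ± 0.127 in arid control roots against 12.19 ± 0.028 in wild-type control roots (mean ± SD, n = 2).

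Some lists of genes also differed in their response, with the preset correlation alone. Of 22 reference genes 16 had a lower fitted response in the mutant, with a median difference of −1.15, 6 genes at an unadjusted p under 0.05 and 0 calls, or 2 adjusted over the list alone (camera, adjusted p = 1.68e-05, adjusted p = 0.141 with an estimated correlation). Of 8 LEA proteins 7 had a lower fitted response, with a median of −1.31, 0 calls and 1 gene at an unadjusted p under 0.05 (camera, adjusted p = 0.0068, adjusted p = 0.431 with an estimated correlation, 0.139 with every probe set of each gene in place of 1). Heat shock genes, with 31 of 43 lower, had a median of −0.73 (camera, adjusted p = 0.00238, adjusted p = 0.765 with an estimated correlation). Other median differences were those of the shoot genes at −1.26, ABA receptors and SnRK2 kinases at −0.49, aquaporins at −0.21 and PP2C phosphatases at −0.10 (camera, adjusted p = 0.0192, 0.0227, 0.0227 and 0.0315, adjusted p = 0.294, 0.294, 0.389 and 0.294 with an estimated correlation). After quantile normalization the medians of the last 2 were −0.49 and −0.27, so their size depended on array scaling. Of 12 histones and mitotic cyclins 11 gave a higher difference, with a median of 0.94 (camera, adjusted p = 0.0185, adjusted p = 0.431 with an estimated correlation). Of 36 jasmonate genes 31 gave a higher difference, with a median of 0.96 (camera, adjusted p = 0.0496, adjusted p = 0.832 with an estimated correlation). In all of these lists 0 genes were called. Taken with the dehydrated arrays numbered 1 and with those numbered 2, the median difference was −1.34 and −0.45 for heat shock genes, 1.44 and 0.35 for jasmonate genes and −0.75 and −0.71 for shoot genes. It was −1.17 and −1.23 for the reference genes, with 19 and 16 of 22 lower, and −1.64 and −1.23 for LEA proteins. Median arid minus wild-type differences in control and in dehydrated roots were 0.968 and −0.085 for the reference genes and 0.923 and −0.24 for LEA proteins. They were 0.855 and 0.105 for heat shock genes and −0.905 and 0.025 for histones and cyclins. These lists thus differed more in control roots, and their levels after dehydration lay closer together. The reverse held for jasmonate genes (−0.208 and 0.325), shoot genes, ABA receptors and aquaporins.

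In all, 85 probe sets were called with a higher and 67 with a lower response in the mutant, 152 together, 51 of them among the dimmer probe sets. Of all probe sets, 3283 had an unadjusted p under 0.05, against 2863 expected by chance over all 57258. That expectation is too high, since the 19933 probe sets at the lowest value on all arrays cannot reach such a p. Median centring moved the split to 91 and 42. With the filter on dim probe sets 83 were higher and 36 lower, of which 53 and 25 were among the 152, and counted as genes 31 and 11 of the 152 remained. The count was 3295 with only the dehydrated arrays numbered 1 (1390 higher and 1905 lower), 3016 with only those numbered 2 (1038 and 1978), and 87 for a difference of at least 1. It was 851 and 1010 without the dehydrated arid replicates (662 and 189, 860 and 150) and 1113 and 1279 without the wild-type control replicates (996 and 117, 1078 and 201). Far more were lower without either arid control replicate or either dehydrated wild-type replicate. This split too followed the group left with 1 array and not a particular array. Of the 7 named genes called here, 5 stayed called without arid control replicate 2 or dehydrated arid replicate 1, 6 without dehydrated arid replicate 2 or wild-type control replicate 1, and 7 without any other array.

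**Figure D3:**
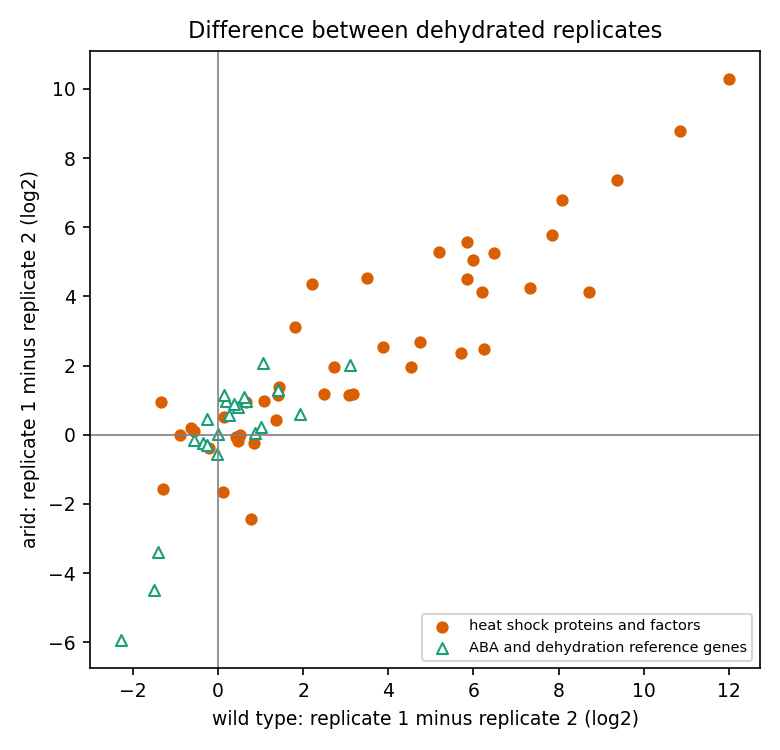
The difference between dehydrated replicates 1 and 2 (log2) is plotted for wild type against the arid mutant, with filled circles for the 43 heat shock genes and open triangles for the 22 reference genes. The heat shock genes reach 12.01 in wild type and 10.29 in the mutant, with medians of 2.72 and 1.97.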

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

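The tests that weigh explanations for the control roots, the values per replicate number and the reading of the ribosomal RNA probe sets were chosen only after the results were seen, whereas the interaction and its list tests were planned. The test of the interaction called 152 probe sets, and the count was larger with any 1 array left out. Of the 152, 51 were among the dimmer probe sets, where most false calls of the simulated comparison lay. With the filter on dim probe sets 53 of those higher and 25 of those lower stayed called. The named genes among them were CML27 (1.71), ACO1 (−3.75) and OsP5CS2 (a fitted 2.91, with arid control roots at the floor and wild-type roots near background), as mutant response minus wild-type response on the log2 scale. OsCslF8, CHLP, BHLH004 and OsC3H9 had fitted values of 2.80, 1.93, 4.17 and 3.82, which bound nothing, since the dehydrated wild-type and both arid groups lay at the floor or near background. Lists whose responses differed were the reference genes (adjusted p = 1.68e-05), heat shock genes (0.00238), LEA proteins (0.0068), histones and cyclins (0.0185), shoot genes (0.0192), ABA receptors and SnRK2 kinases (0.0227), aquaporins (0.0227), PP2C phosphatases (0.0315) and jasmonate genes (0.0496), by limma's camera with its preset correlation, and 0 of them with an estimated correlation. With the dehydrated arrays numbered 1 and with those numbered 2 the median difference was −1.34 and −0.45 for heat shock genes, 1.44 and 0.35 for jasmonate genes, −1.64 and −1.23 for LEA proteins and −1.17 and −1.23 for the reference genes. The reference genes differed between the genotypes by a median of 0.968 in control and −0.085 in dehydrated roots. Their lower response thus went with a higher level in arid control roots. The same held for heat shock genes (0.855 and 0.105).

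Ribosomal RNA probe sets, which belong to the control probe sets outside the tests, were brighter on dehydrated than on control arrays by 2.61 for 5.8S, 1.41 for 18S, 1.28 for 25S and 1.39 for 28S on the log2 scale. In wild type and in the mutant apart, the rise was 2.79 and 2.44 for 5.8S, 1.58 and 1.25 for 18S, 2.06 and 0.50 for 25S, and 2.06 and 0.72 for 28S, and these genotype differences were not tested.

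Of 428 brighter probe sets called lower in the arid control group, 392 (91.6%) were lower in dehydrated than in control wild type. Both comparisons use the wild-type control arrays, and simulations without any effect gave 91.8% for as many of the lowest probe sets. Of the 428, 235 were called in both, against 108 in these simulations, which correlate at 0.499 with a covariance of 0.221 (observed 0.295 and 0.531). The simulations gave every array the spread pooled over the 4 groups, while the spread of the wild-type control arrays alone gives a covariance of 0.076. They thus overstate the effect of the shared arrays, and neither the share nor the overlap can decide on a link. When each comparison took a different wild-type control array the correlation was 0.244 or 0.245. This argues against chance values of single shared arrays as the whole cause, although much of the overlap may come from them. A chance deviation common to both wild-type control arrays would remain after this split, so it is not excluded. A hypothesis is that arid roots may already show a mild form of the dehydration response in control conditions. The 500 probe sets most raised in wild type were higher in arid control roots by a median of 0.353, or 0.422 with the control arrays exchanged, with 67.2% and 67.4% higher. Against it, of 233 brighter probe sets called higher in arid control roots only 99 (42.5%) were higher in dehydrated wild type. The shared wild-type control arrays push this share up as well, and its value without any effect was not simulated. Fewer growing and dividing cells cannot be told apart from such a mild response, since 11 of 12 histone and cyclin genes were lower in arid control roots and 11 of 12 also in dehydrated wild type. A genotype effect on growth, like a difference in handling of these 2 plant groups, stays open and untested.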

How the results depend on the processing

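Named changes that were called kept their direction under the alternatives tried, but this was largely fixed in advance. Most alternatives change the variance or the set of tests and leave the fitted change as it is. The largest named changes were also chosen for arrays that did not overlap between the groups. The counts moved with most choices. With some array left out, the majority of higher or lower probe sets turned to the other side in each of the 5 comparisons. The other array of the same group gave the same turn, so it followed the group left with 1 array and not a particular array. Counts are given in the order dehydration in wild type, dehydration in the mutant, genotype in control, genotype after dehydration and interaction, beside 1685, 557, 720, 115 and 152. The cause was not tested except where fewer probe sets, arrays or adjusted tests enter by construction. The filter on dim probe sets gave 3709, 1213 and 1586 for the first comparisons and stayed within 1.5 times for the others. Robust variances gave 697, 146, 318, 64 and 77. Array weights, equal within each group of 2, gave 952, 304, 3341 and 55. Fits on the compared groups alone gave 86, 46, 112 and 51, and the interaction has none, since it uses all 4 groups. Adjustment over all 5 contrasts gave 825 in wild-type dehydration, 225 between the dehydrated genotypes and 230 for the interaction. Genes in place of probe sets, with fewer tests, gave 1014, 310, 391, 42 and 42. A change of at least 1 left 87 for the interaction. Quantile normalization, median centring and the fit without an intensity trend kept all 5 counts within 1.5 times.

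With the replicate number as a block the counts were 507, 70, 187, 27 and 69, and 40 lists were called in place of 39, all 39 among them. Of the named genes called, 21 of 56, 4 of 30, 3 of 28, 1 of 8 and 2 of 7 were called with this block. The numbers were not taken to pair the samples: the differences between replicates 1 and 2 correlated at 0.606 between the dehydrated groups and 0.227 between the control groups, but at −0.213 between arid control and dehydrated arid, −0.134 between wild-type control and dehydrated arid, and 0.011 and 0.016 in the other two pairs of groups. Added after seeing the data, the crossed replicate block gave 103 for dehydration in the mutant, and a replicate block within each condition gave 39, 16 and 34 for the genotype comparisons and the interaction, with 0 of 28, 0 of 8 and 1 of 7 named genes called.

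Also added after seeing the data, a filter on floor values gave 3306, 1098 and 1426 for the first comparisons. With only the dehydrated arrays numbered 1 the counts were 7110, 5022, 3494 and 3295, and with only those numbered 2 they were 5412, 2032, 3493 and 3016, leaving out the control comparison, and the response correlation fell to 0.613 with the latter. Leaving out 1 array at a time gave 315 to 3140, 74 to 2550, 326 to 2602, 43 to 1961 and 851 to 2107, and a response correlation of 0.485 to 0.764 around 0.711. A group left with 1 array was assumed to vary like the others. Estimated correlations left 2 of 39 list calls. Tests with every probe set of each gene or with the dim filter called 41 and 45, with 37 and 39 of the 39 among them. Of 4987 values of named genes, lists and shared calls under alternatives, 3710 stayed as they were by these measures, 1123 lost and 48 gained a call. A further 106 counts or values without a call moved, and 0 reversed, which for named genes was largely fixed in advance. Of 56 named genes called for dehydration in wild type, 1 stayed called with only the wild-type arrays, and with only the compared groups 1 of 30, 0 of 28 and 0 of 8 in the next comparisons. The targeted gene was not analysed here under any setting. Signal near the floor limits the folds of dim probe sets.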

Other observations

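The comparison of dehydrated replicates and the tests of RNA quality, array scaling, progress of the response, linkage and base changes under probes were chosen only after the results were seen. The dehydrated arrays numbered 1 and 2 differed in some lists. Besides the heat shock genes, the 6 WRKY factors had median differences (replicate 1 minus replicate 2) of −2.11 in wild type and −1.22 in the mutant, the 12 anaerobic response genes of −1.06 and −2.09, and the 36 jasmonate genes of −1.56 and −0.35. The medians were −0.54 and −0.03 for pathogenesis-related proteins, 0.28 and 0.00 for aquaporins, and −0.03 and −0.56 for osmoprotectant genes, and whether the genotypes differ in this was not tested.

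Of 43 heat shock genes 37 were higher in replicate 1 of dehydrated wild type and 34 in replicate 1 of dehydrated arid roots, 31 of them in both. They were led by HSP26.7 (12.01 and 10.29), HSP21.9 (10.86 and 8.79), HSP16.9B (9.38 and 7.35) and hsp101 (8.07 and 6.80), named outside the rule after their values were seen. In both genotypes the median lay above all 10000 random lists matched on mean expression (percentile 100). This is no separate support, since the list was singled out in the same data. The random lists also drew genes independently, so any list of genes that vary together can lie far out. Anaerobic response genes lay at percentiles 0.0 and 0.0 and WRKY factors at 0.01 and 0.4. Against control the heat shock median was 3.06 and 1.71 with replicate 1 but 0.03 and −0.44 with replicate 2. Array scaling is argued against by medians that remained at 2.63 and 1.94 after quantile normalization. RNA quality cannot be told apart, since the 3′ minus 5′ values of GAPDH and actin differed less between dehydrated replicates (at most 0.18 and 0.24) than between control replicates (0.48 and 0.43), but that of cyclophilin more (0.49 against 0.08) and lower on replicate 1 in both genotypes, where the 18S, 25S and 28S probe sets were also lower. That the arrays numbered 1 could be further along the same response stays open, as the reference genes differed by medians of 0.235 and 0.51, too little to decide, and no other biological explanation was tested, since the labels give no temperature or day for a replicate number.

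Of the probe sets tested, 51 were called in both genotype comparisons, 49 with the same sign (36 higher and 13 lower in the mutant) against 0.315 and 0.373 in independent lists, which leave out the variances shared by both tests. A linked stretch of genes around the insertion or a crossed-in segment is argued against as the whole cause by the gene order of the assembly ASM3414082v1: the 31 genes with a place in it formed 4 neighbouring pairs within 100 genes, against a mean of 2.44 in 2000 random sets, 20.5% of which had as many. Base changes under single probe sets cannot be told apart from changed expression, since among 5 other probe sets of these genes above the floor 3 had the same sign in both conditions and 1 differed by over 1, too few to decide. LOC4331398 and LOC9268308, named after their values were seen, were called by 2 probe sets each. Whether the insertion or the background of this line gives these differences cannot be read from 1 mutant line and stays untested.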
